A study of Zea mays with 10 samples.

How the data were processed

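RNA was measured in 10 maize libraries, 2 in each of 5 groups: B73 anthers before meiosis, and anthers and isolated male germ cells at prophase I from B73 and from ms28. B73 is the inbred line whose genome serves as the maize reference, and ms28 is a male-sterile mutant. Whether ms28 was bred into B73 was not established here. What is called an ms28 effect below may therefore include other differences between the lines. Per the labels' protocols, total RNA was made into libraries with a Smart-seq type method, which copies RNA into cDNA by template switching and amplifies it by PCR, followed by tagmentation and paired-end Illumina sequencing. This kind of library does not mark the strand, so reads from overlapping antisense transcripts cannot be told apart. Per the labels' protocols, plants grew either in a field or in a greenhouse. Which of these each library came from is not given in the sources used here, and nothing says that the 2 libraries of a group came from separate plants. The p-values therefore measure only the spread between these libraries, which may be technical.

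The submitters' processing notes list Trimmomatic 0.33, HISAT2 2.2.1, Cufflinks, featureCounts 2.0.1 and DESeq2 with the genome build B73 RefGen_v4, without saying which step made which table. Of the 3 deposited tables, 2 hold TPM values, per the file headers, for the prophase I anthers and the prophase I male germ cells. Each deposited TPM column summed to between 99.1 and 99.4% of 1000000, so TPM in these tables is a share of the RNA of a library and keeps no sequencing depth. The unit of the deposited premeiotic table is not given in the sources used here, and its columns summed to 83.0 and 83.2% of 1000000. That table held 1 value below 0 (-1e-06), which was set to 0 for ranking. Depth per library is unknown, because no total counts were used here, and no counting interval is given. A count model was not run, since the values are not counts. The prophase I columns were matched to groups through the header lines of each table (genotype and replicate) and the tissue and stage that the table's own name gives, with WT read as B73.

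The tables held 25460 features for prophase I anthers, 22786 for germ cells and 43789 for premeiotic anthers. Nearly all IDs were gene models of the form Zm00001d plus a number, and 49 rows were miRNA loci named zma-MIR. The reference gene table used here, of assembly Zm-B73-REFERENCE-NAM-5.0, matched 0 of the 43789 gene models and 48 of the 49 miRNA loci. It is of another build, so no coordinates are given. All 16 gene lists fixed before the data were examined, from meiosis and tapetum genes to small RNA machinery, therefore matched 0 features and were not tested. The mutated locus of ms28 could not be looked up by name either, so the labels were not checked by it. Gene models are given by ID only.

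The 8 prophase I libraries were fitted together with limma-trend 3.58.1 in R 4.3.3 on log2(TPM + 1), with 1 coefficient per group and no replicate block. The fit used the 20892 features at 1 TPM or more in at least 2 libraries, out of 22402 features in both tables. Contrasts were ms28 against B73 in anthers, the same in germ cells, the difference between those effects, and germ cells against anthers in B73. Features with a Benjamini-Hochberg adjusted p under 0.05 are called, and a log2 change is on the log2(TPM + 1) scale, which understates the change of low features. Anthers and germ cells stand in separately filtered tables, so tissue and table cannot be separated in the last contrast. The premeiotic table was not tested against the others. Its features were compared with the prophase I anthers by percentile rank over the 25412 features in both tables. Analysis tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

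The fit was tested on simulated data for the anther comparison, with 50 features planted at each of 4 sizes among 20892. It recovered 20% at a log2 change of 1, 96% at 2, 96% at 3 and 98% at 4, with 10 false calls. The simulated noise was independent and normal, with the same spread in every group and no shift of whole libraries. Features were planted only where the B73 anther mean lay between 3 and 10 on the log2 scale. The real libraries shifted and differed in spread between groups, so these rates need not hold for them. The naming rule, fixed before the data were examined, named features with an informative reference name and a mean of at least 10 TPM in the higher group, and otherwise 2 IDs that rose and 2 that fell by smallest adjusted p. For features with a name it also asked that both libraries of 1 group lie above both of the other. It also named the 5 features with the smallest adjusted p among those called in the same direction in both tissues. Here only miRNA loci had names. The minimum of 10 TPM and the order of the libraries were applied in the comparisons of 2 groups but not to the interaction. There all called miRNA loci were named, among them MIR167d with a mean below 10 TPM in every group. The other miRNA loci in the text, the premeiotic examples and those gene models of the closing section that the rule did not name were chosen after their values were seen.

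Alternatives planned before the data were examined were quantile normalization, no low filter or one at 5 TPM, a pseudocount of 0.1, only the compared libraries, a replicate block, a fold threshold, an adjusted p under 0.01, and leaving out each library. Chosen after seeing the data were centring each library on its median feature, a fit of each table alone with all its features, and centring combined with leaving out either B73 anther library.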

Results

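The series asks which maize transcripts respond to 21-nt phasiRNAs, the phased small RNAs that accumulate in grass anthers. The RNA-seq part covers B73 anthers before meiosis (2 libraries) and prophase I anthers and male germ cells of B73 and the male-sterile mutant ms28 (2 libraries in each of 4 groups). The median feature of the anther table stood at 8.27 and 6.65 TPM in the B73 anther libraries and at 4.45 and 4.66 TPM in the ms28 anther libraries. The 100 most abundant features held 19.6 and 28.0% of TPM in B73 anthers against 39.2 and 34.9% in ms28 anthers. In germ cells they held 22.3 and 22.5% in B73 and 20.8 and 21.4% in ms28. Over 15634 features, the SD of the log2 difference between the libraries of a group was 0.199 in premeiotic anthers, 0.574 in B73 anthers, 0.457 in ms28 anthers, 0.507 in B73 germ cells and 0.360 in ms28 germ cells.

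The first comparison asks how ms28 anthers at prophase I differ from B73 anthers. Among named transcripts, the precursor of MIR2275b rose from 14.6 ± 2.60 to 62.8 ± 16.8 TPM (SD, n = 2 per group). MIR2275 is the miRNA family that triggers the longer class of reproductive phasiRNAs. MIR399d, of a family known from the phosphate starvation response, rose from 10.3 ± 1.55 to 96.2 ± 35.2 TPM (SD, n = 2). MIR171f, of a family that targets GRAS transcription factors, fell from 51.5 ± 6.41 to 2.09 ± 2.95 TPM (SD, n = 2). In each of these loci both ms28 libraries lay on the same side of both B73 libraries, as the naming rule required. Of all tested features, 3.44% lay higher and 68.7% lower in both ms28 anther libraries than in both B73 anther libraries. The log2 changes were 2.02 (SE 0.38, adjusted p = 0.029) for MIR2275b, 3.06 (SE 0.51, adjusted p = 0.022) for MIR399d and -4.52 (SE 0.67, adjusted p = 0.017) for MIR171f in the limma fit. The median of all tested features was itself lower in ms28 anthers, by a log2 change of -0.48. With each library centred on its median feature the 3 changes were 2.54, 3.59 and -4.00, and all were called (adjusted p = 0.024, 0.015 and 0.032).

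Of the 25 miRNA loci tested in anthers, 4 were called over all features and 4 when adjusted over the list alone. The locus not yet named is MIR167d, of a family that targets auxin response factors. It fell from 3.70 to 0.715 TPM (log2 -1.44, adjusted p = 0.018), a call that ended with centring (log2 -0.92, adjusted p = 0.137). MIR2275a, present in the anther table only, read 7.30 ± 0.70 TPM in B73 and 44.5 ± 15.4 TPM in ms28 (SD, n = 2). Within that table alone its log2 difference was 2.42 with an adjusted p = 0.068. MIR2275c, the most abundant miRNA locus in B73 anthers, read 2517 ± 1696 TPM in B73 and 1012 ± 354 TPM in ms28 (SD, n = 2) and was not called (adjusted p = 0.140). None of the 3 loci of MIR2118, the family that triggers 21-nt phasiRNAs, was called, and MIR2118g read 11.7 ± 1.78 and 9.92 ± 2.09 TPM (SD, n = 2). The values of MIR159b, MIR159g, MIR159h, MIR159j and MIR159k were close to each other within each library, and reads that these copies may share leave their levels uncertain.

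**Figure D1:**
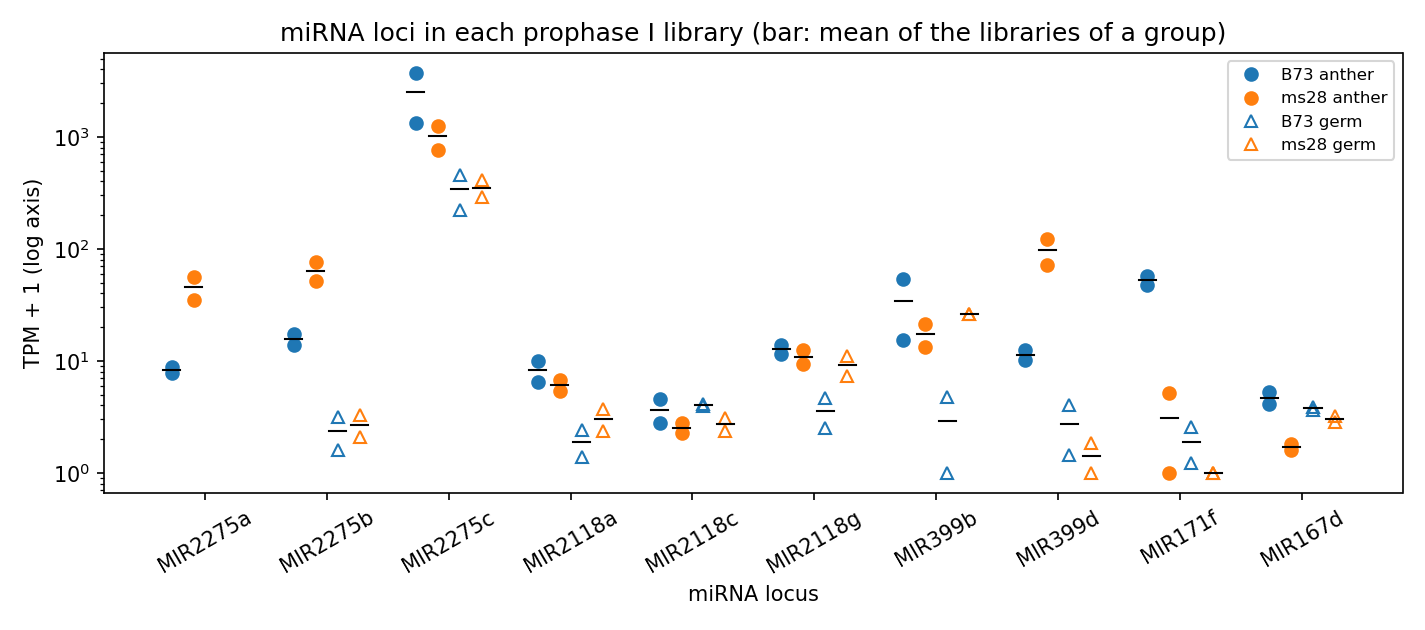
Level of 10 miRNA loci in each prophase I library as TPM + 1 on a log axis, with circles for anthers, triangles for male germ cells, blue for B73, orange for ms28 and a bar for the mean of the 2 libraries. MIR2275b and MIR399d are higher and MIR171f lower in both ms28 anther libraries than in both B73 anther libraries, and MIR2275a is in the anther table only.

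Among gene models, Zm00001d041772 rose from 0.235 ± 0.064 to 33.7 ± 11.1 TPM and Zm00001d019372 from 0.180 ± 0.071 to 7.08 ± 0.20 TPM in ms28 anthers (SD, n = 2). Zm00001d009902 fell from 115 ± 37.6 to 0.055 ± 0.021 TPM and Zm00001d012806 from 55.5 ± 27.8 to 0.015 ± 0.021 TPM (SD, n = 2). Their adjusted p lay between 0.00015 and 0.00057. Mean TPM in B73 and ms28 germ cells was 0.031 and 4.35 for Zm00001d041772 and 0.055 and 4.12 for Zm00001d019372. It was 26.0 and 0.108 for Zm00001d009902 and 49.1 and 0.018 for Zm00001d012806. In anthers 1633 features were called in all, 106 higher and 1527 lower in ms28, and the split changed with the scaling. Centring gave 152 higher and 127 lower, and quantile normalization 148 higher and 170 lower. Under both TPM as deposited and centring, 231 features were called, 104 higher and 127 lower, and by centred values 119 of them changed at least 4-fold (49 higher and 70 lower).

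The number of anther calls rested on single libraries. It was 303 without B73 anther replicate 1, 4241 without B73 anther replicate 2, 59 and 281 without ms28 anther replicates 1 and 2, and 132 without either ms28 germ cell library, against 67 in a fit of the anther table alone. In that fit 0 of 34 miRNA loci were called by limma, and 9 had an unadjusted p under 0.05. MIR399d missed the threshold (adjusted p from 0.0504 to 0.123) without B73 anther replicate 1, ms28 anther replicate 1 or either ms28 germ cell library. MIR2275b missed it (from 0.0653 to 0.149) without those libraries or without ms28 anther replicate 2. MIR171f missed it only without ms28 germ cell replicate 1 or 2 (0.0539 and 0.0541), among the fits that left out 1 library. MIR167d missed it (from 0.0531 to 0.0976) without either ms28 anther or either ms28 germ cell library. A pseudocount of 0.1 in place of 1 ended the calls of MIR399d (adjusted p = 0.084) and MIR2275b (0.058).

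**Figure D2:**
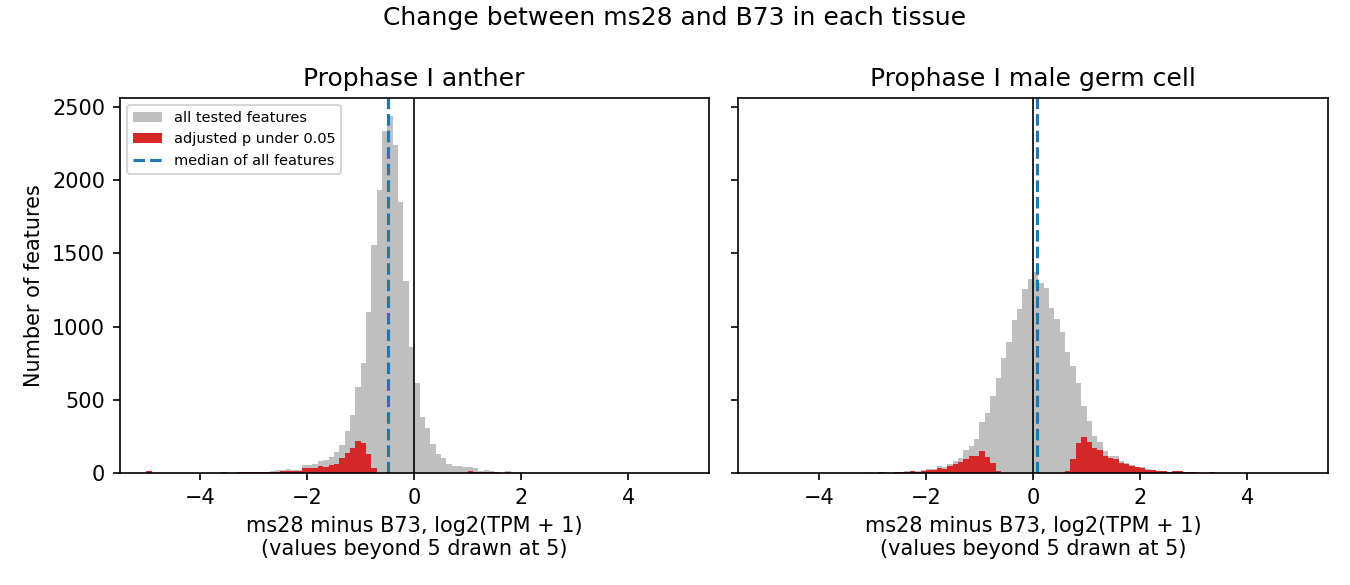
Number of features (y axis) by difference between ms28 and B73 in log2(TPM + 1) (x axis), in prophase I anthers and male germ cells, with all tested features in grey, called features in red and the median of all features as a dashed line. Differences beyond 5 are drawn at 5, and the median lies at -0.48 in anthers and at 0.07 in germ cells.

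The second comparison asks the same of isolated male germ cells. MIR399b rose from 1.89 ± 2.68 to 25.2 ± 0.00067 TPM (SD, n = 2; log2 3.58, SE 0.75, adjusted p = 0.022), with B73 libraries at 0 and 3.79 TPM. MIR2118g, a member of the family that triggers 21-nt phasiRNAs, rose from 2.58 ± 1.48 to 8.15 ± 2.64 TPM (SD, n = 2; log2 1.39, SE 0.35, adjusted p = 0.035). These were the 2 loci called among 25, with 2 also when adjusted over the list alone. Neither other MIR2118 locus was called in the limma fit. MIR2118a had a log2 change of 0.70 (adjusted p = 0.218) and MIR2118c, in the other direction, -0.58 (adjusted p = 0.198). MIR2275c read 338 ± 166 TPM in B73 and 351 ± 88.9 TPM in ms28 germ cells (SD, n = 2; adjusted p = 0.897). MIR399b missed the threshold without B73 germ cell replicate 1 (adjusted p = 0.083) or ms28 germ cell replicates 1 and 2 (0.148 and 0.094). MIR2118g missed it without either ms28 anther library (0.052 each), B73 germ cell replicate 1 (0.144) or ms28 germ cell replicates 1 and 2 (0.232 and 0.075), and under quantile normalization (0.061).

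Among gene models in germ cells, Zm00001d010500 rose from 9.19 ± 0.65 to 181 ± 3.78 TPM (SD, n = 2). Zm00001d003610 was listed at 0 in both B73 libraries and rose to 22.7 ± 1.17 TPM. Zm00001d022937 fell from 51.9 ± 9.47 to 0.045 ± 0.064 TPM and Zm00001d013188 from 97.3 ± 24.0 to 0.974 ± 0.333 TPM (SD, n = 2). Each of these 4 had an adjusted p of 4.9e-05. Their mean TPM in B73 and ms28 anthers was 43.5 and 56.1 for Zm00001d010500 and 0 and 2.90 for Zm00001d003610. It was 11.6 and 0.030 for Zm00001d022937 and 34.5 and 1.03 for Zm00001d013188. In germ cells 2995 features were called in all, 1890 higher and 1105 lower in ms28, and 2934 of them were also called after centring. Quantile normalization evened the split to 1314 higher and 1279 lower. The count was 1161 and 1331 without B73 germ cell replicates 1 and 2, 293 and 574 without ms28 germ cell replicates 1 and 2, and 1946 and 1949 without ms28 anther replicates 1 and 2.

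Some features changed in the same direction in both tissues. The 5 that the naming rule took from this group all fell in ms28: Zm00001d009902, Zm00001d013188, Zm00001d012806, Zm00001d003452 and Zm00001d013031. Zm00001d012806, for example, fell from 49.1 ± 2.24 to 0.018 ± 0.025 TPM in germ cells as well (SD, n = 2). Zm00001d003452 read 19.0 ± 1.47 TPM in B73 anthers and 13.6 ± 4.51 TPM in B73 germ cells (SD, n = 2) and was listed at 0 in all 4 ms28 libraries. With centred values, 83 features rose in both tissues against 16.1 for independent lists, and 51 fell in both against 8.97. With TPM as deposited these counts were 64 against 9.59 and 193 against 80.8. The 2 comparisons share no library, although they share the estimate of the spread. Across genes, which are not independent replicates, the 2 sets of log2 changes had a Pearson correlation of 0.272 and a Spearman correlation of 0.163.

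**Figure D3:**
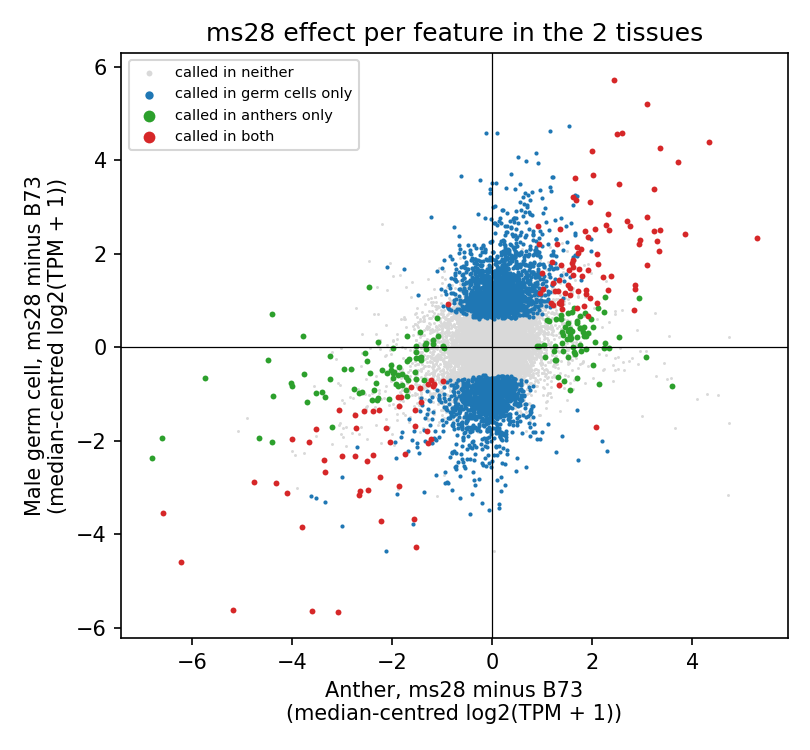
Difference between ms28 and B73 in median-centred log2(TPM + 1) for each tested feature, in anthers (x axis) and male germ cells (y axis), coloured by where the feature was called. Features called in both tissues lie mostly along 1 diagonal, with 83 higher in both and 51 lower in both.

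The effect of ms28 was also tested for a difference between the tissues. MIR399d had the higher ms28 effect in anthers, with an interaction of -3.89 on the log2 scale (SE 0.71, adjusted p = 0.022), and read 1.72 ± 1.81 TPM in B73 and 0.419 ± 0.592 TPM in ms28 germ cells (SD, n = 2). MIR399b, MIR171f and MIR167d had positive interactions of 4.34, 3.70 and 1.13 (adjusted p = 0.037, 0.041 and 0.048). MIR171f was near the floor in B73 germ cells (0.212 and 1.58 TPM) and listed at 0 in both ms28 germ cell libraries, so its change there could not go below -0.82 on this scale and its interaction does not show a difference between the tissues. The 3 calls ended with centring (interactions of 3.81, 3.17 and 0.60, adjusted p = 0.087, 0.103 and 0.324) and with quantile normalization (0.118, 0.120 and 0.440), and those of MIR399b and MIR171f with a pseudocount of 0.1 (0.070 and 0.275). That of MIR399d held with centring (-4.42, adjusted p = 0.034) and ended with the pseudocount of 0.1 (0.0501). For MIR2275b the interaction was -1.80 (adjusted p = 0.057). Over the 25 loci, 4 were called over all features and 6 when adjusted over the list alone. Zm00001d010500 stood at 43.5 ± 2.06 TPM in B73 and 56.1 ± 1.51 TPM in ms28 anthers (SD, n = 2), beside its rise in germ cells (interaction 3.80, adjusted p = 0.0023). Zm00001d036272 read 16.1 ± 1.75 and 12.1 ± 2.41 TPM in anthers against 16.5 ± 4.31 and 0.592 ± 0.108 TPM in germ cells (SD, n = 2; interaction -3.05, adjusted p = 0.0088).

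In all, 3009 features had an ms28 effect that differed between the tissues. For 2902 of them the difference, germ cells minus anthers, was positive, which a fall in anthers alone would also give. The median log2 change of all tested features was -0.48 in anthers and 0.07 in germ cells. Centring left 319 calls (217 positive and 102 negative) and quantile normalization 221 (150 and 71). Without ms28 germ cell replicate 1, limma called 0 features, with 5231 at an unadjusted p under 0.05, and without replicate 2 it called 4. The count was 1508 without B73 anther replicate 1, 219 and 482 without ms28 anther replicates 1 and 2, and 392 without B73 germ cell replicate 1. Without ms28 germ cell replicate 1 the adjusted p of MIR399d was 0.102 and that of Zm00001d010500 was 0.0596, and without replicate 2 that of MIR399d was 0.0651. MIR399d also missed the threshold without ms28 anther replicate 1 (0.0737). Zm00001d036272 missed it without ms28 germ cell replicate 1 or 2 (0.0655 and 0.0588). MIR399b missed it without any 1 library except B73 anther replicate 2 and B73 germ cell replicate 2 (from 0.0640 to 0.128), MIR171f without any except B73 anther replicate 2 and ms28 anther replicate 2 (from 0.0537 to 0.135), and MIR167d without any 1 of the 8 (from 0.0526 to 0.130).

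Germ cells were next compared with whole anthers in B73 at prophase I. Precursors of miRNAs were mostly lower in germ cells: of 25 loci, 19 were lower, 2 were higher and 4 were not called, with 22 called when adjusted over the list alone. The lower loci became 13 without B73 germ cell replicate 1, 14 without B73 anther replicate 1 and 13 at an adjusted p under 0.01, and 5 of the 19 are the MIR159 copies of uncertain level. MIR171f stood at 51.5 ± 6.41 TPM in anthers and 0.894 ± 0.965 TPM in germ cells (SD, n = 2; log2 -4.89, SE 0.67, adjusted p = 0.00039). MIR2275c was lower at 338 ± 166 TPM against 2517 ± 1696 TPM (SD, n = 2; log2 -2.80, adjusted p = 0.0019). MIR528a, of a monocot family that targets copper proteins, stood at 5.57 ± 4.68 TPM in germ cells and 54.3 ± 5.69 TPM in anthers (SD, n = 2; adjusted p = 0.0011). MIR167g, MIR169o and MIR399b were lower by log2 changes of -3.06, -3.18 and -3.71, which ran from -2.71 to -3.42, -2.62 to -3.74 and -2.58 to -4.84 when 1 library was left out. Of the MIR2118 loci, MIR2118a and MIR2118g were lower (log2 -2.15 and -1.89, SE 0.37 and 0.35), and MIR2118c was not called (0.18, adjusted p = 0.590). The 2 higher loci were MIR169c and MIR169j, of a family that targets NF-YA transcription factors (log2 2.22 and 1.22, SE 0.43 and 0.30).

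The median tissue change of the 25 loci was -2.09 against -0.36 for all tested features. As a set the loci were lower by limma's camera with a preset correlation (p = 0.0056, adjusted p = 0.011 over the 4 comparisons), and p = 0.283 with an estimated correlation. In the same family of tests the loci stood above other features in the ms28 anther comparison (adjusted p = 0.011), although their median there was -0.41, and this ended with an estimated correlation (p = 0.266) and with centring (adjusted p = 0.749). The germ cell and interaction comparisons gave an adjusted p of 0.699 and 0.083. This set was formed after the data were seen.

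Gene models higher in B73 germ cells included Zm00001d006236, at 666 ± 169 TPM against 11.7 ± 3.44 TPM in anthers, and Zm00001d016163, at 130 ± 1.32 against 9.20 ± 1.76 TPM (SD, n = 2). Those lower included Zm00001d030328, at 0.590 ± 0.079 TPM against 146 ± 14.5 TPM, and Zm00001d034635, at 8.51 ± 1.99 against 703 ± 38.5 TPM (SD, n = 2). In all, 14247 features were called, 5645 higher and 8602 lower in germ cells, and 13873 of them were also called after centring. Quantile normalization turned the split to 7191 higher and 6176 lower. Both groups come from tables that were filtered separately, so a difference between the tables would count as a difference between the tissues.

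Prophase I anthers of B73 were set beside premeiotic anthers by rank only, since the tables were normalized separately. Of 25412 features in both tables, 182 stood at least 50 percentile points higher in both prophase I libraries than in both premeiotic ones, and 14 stood at least 50 points lower. Zm00001d003232 moved from percentiles 7.42 and 5.62 to 97.2 and 94.2, and Zm00001d002839 from 5.12 and 4.66 to 97.4 and 91.9. Zm00001d024000 moved from 88.7 and 87.3 to 8.20 and 9.87, and Zm00001d013724 from 83.4 and 85.2 to 11.7 and 14.8. Between the 2 premeiotic libraries 4 features differed by that much, and between the 2 B73 prophase I libraries 51. Of the 182 features, 89.0% ranked higher in B73 anther replicate 1 than in replicate 2. The prophase I anther table leaves out 18377 premeiotic features, so their falls could not be seen, and 70 of these were among the 8581 at 10 or more in both premeiotic libraries.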

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

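The tests of the most abundant features and of B73 anther replicate 1, and centring, were chosen after the results were seen. The results below stand here because the interaction test found that the ms28 effect differed between germ cells and anthers. It called 3009 features with TPM as deposited and 319 with centred values. Of the miRNA loci, MIR399b (4.34), MIR171f (3.70) and MIR167d (1.13) had positive interactions on the log2 scale, all of which lost their call with centring, and MIR399d (-3.89) had a higher effect in anthers. The value of MIR171f is set by the floor, since it was near 0 in germ cells of both genotypes, and does not show an effect that differs by tissue. Of the gene models, Zm00001d010500 (3.80) and Zm00001d002052 (5.24) had positive interactions, each with a rise in germ cells. Zm00001d036272 (-3.05) and Zm00001d036270 (-2.70) had negative interactions, each with a fall in germ cells that anthers did not match. Zm00001d002052 read 0.624 ± 0.431 TPM in B73 and 37.4 ± 2.23 TPM in ms28 germ cells, and 32.5 ± 2.55 and 20.3 ± 1.51 TPM in anthers (SD, n = 2). Zm00001d036270 read 18.7 ± 1.89 and 2.37 ± 0.18 TPM in germ cells, and 12.1 ± 2.16 and 13.6 ± 3.41 TPM in anthers (SD, n = 2). Without ms28 germ cell replicate 1 limma called 0 features for this difference (5231 at an unadjusted p under 0.05), so none of those named kept its call, and without ms28 germ cell replicate 2 it called 4.

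Of the 3009 interaction calls 2902 were positive, and in ms28 anthers 1527 of 1633 calls were falls. The number of falls rested on single libraries, being 254 of 303 calls without B73 anther replicate 1 and 4040 of 4241 without replicate 2. The direction was not carried by B73 anther replicate 1 alone: the median log2 change of all tested features was -0.37 without it, -0.59 without replicate 2 and -0.48 with all libraries. With the 100 most abundant features of each anther library left out (151 features) and TPM rescaled, the median of the others was -0.24. The features left out held 22.7 and 31.6% of TPM in B73 and 43.0 and 39.6% in ms28 anthers. Leaving them out therefore had to raise the median, whatever the cause. Since -0.24 remained, the share of these 151 was not the whole of the shift. Leaving out the top 500 of each library (668 features) brought it to -0.14, so what remains depends on how many are left out. A broad shift of RNA towards abundant transcripts in ms28 anthers may be the ms28 effect itself or another difference between the lines. It may also be a difference in stage or library preparation between the 2 pairs of libraries, and the design leaves this open.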

How the results depend on the processing

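Centring, the fits of each table alone and centring with a B73 anther library left out were chosen after seeing the data. The named results were picked from these same data, the gene models by smallest adjusted p, which favours kept calls. Changing only the filter, the block, the threshold or the libraries of other groups left the log2 change as it was. No reversal could arise in those settings. Of 37 named results recomputed under the alternatives, 636 of 713 values kept their call, 77 lost it and 0 reversed. The settings with the most losses were those without ms28 germ cell replicate 1 (12) and 2 (10). The 1633 anther calls became 318 with quantile normalization, 279 with centring, 70 with only the compared libraries, 67 with the anther table alone, 72 at an adjusted p under 0.01, and 197 and 636 with centring and without B73 anther replicate 1 or 2. The 2995 germ cell calls became 591 at an adjusted p under 0.01. The 3009 interaction calls became 221 with quantile normalization, 319 with centring, 103 at an adjusted p under 0.01, and 378 and 456 with centring and without B73 anther replicate 1 or 2. Leaving out 1 library gave 59 to 4241 calls in anthers, 293 to 4092 in germ cells, 0 to 4475 for the interaction (5231 features at an unadjusted p under 0.05 in limma where it gave 0) and 11627 to 13787 for tissue; a lone library is then assumed to vary like the other groups. The tissue count of 14247 stayed within 1.5 times under all 19 alternatives. The replicate numbers were not taken to pair the samples: across genes, the differences between replicates 1 and 2 correlated at 0.144 between B73 anthers and B73 germ cells, and at -0.081 to 0.026 in the other 5 pairs of groups. With a replicate block the counts were 1046 in anthers, 2256 in germ cells, 1870 for the interaction and 14019 for tissue, and the interaction calls of MIR399b (adjusted p = 0.0521) and MIR167d (0.0701) ended. Apart from the stricter threshold, which lowers a count by definition, the cause of these changes was not tested. Count-based tests could not be run on TPM, and depth is unknown, so the precision of low features is unknown too.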

Other observations

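The tests in this part were chosen after the results were seen. Some of the most abundant anther transcripts differed widely between the B73 libraries. Of 10 features at 5000 TPM or more in both ms28 anther libraries, 4 read 56.0 to 374 TPM in B73 anther replicate 1 and 6205 to 12963 TPM in replicate 2. Zm00001d001829, for example, read 169 and 12963 TPM in B73 anther replicates 1 and 2, and 42159 and 18116 TPM in the ms28 anthers. Zm00001d052736 read 56.0 and 6205 TPM in B73 and 18273 and 6512 TPM in ms28. In germ cells these 4 were highest in B73 replicate 2 (166 TPM for Zm00001d001829 and 173 TPM for Zm00001d052736). B73 anther replicate 2 resembled the ms28 anthers about as much as its own replicate. Its correlation across genes was 0.957 with B73 anther replicate 1, and 0.956 and 0.963 with ms28 anther replicates 1 and 2. B73 anther replicate 1 stood at 0.928 and 0.940 with those 2, and the ms28 anthers at 0.977 with each other. By correlation across genes with premeiotic replicate 1, B73 anther replicate 1 stood at 0.831, B73 anther replicate 2 at 0.901 and the ms28 anthers at 0.869 and 0.871. The germ cell libraries stood at 0.683 and 0.725 in B73 and 0.773 and 0.772 in ms28, and the ms28 ones were also closer to prophase I anthers (with B73 anther replicate 2, 0.733 and 0.785 in B73 and 0.810 and 0.816 in ms28).

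Features called in the same direction in both tissues gathered at 1 stretch of gene numbers, which run along the chromosomes in this annotation. Of 134 such features with centred values, 20 lay within 500 numbers, from Zm00001d012786 to Zm00001d013188, where random sets of the same size had a median of 6 and at most 10 (permutation p = 0.0001, the smallest that 10000 sets can give). Random draws from features called in germ cells only reached at most 12. A block of linked variants carried along with ms28 may account for this. A single block needs the stretch to lie on 1 chromosome, which was not checked, since only gene numbers were used. Loss of reads from alleles unlike B73 would not by itself give the 7 rises among the 20, but other alignment errors were not tested. For the 13 falls, 11 of which were below 1 TPM in ms28 in both tissues, lost reads and lost transcripts cannot be told apart without the reads.

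More features rose than fell in ms28 male germ cells, except that quantile normalization evened the split (1314 and 1279). RNA from the rest of the anther, with the makeup of the ms28 anther libraries, would bring abundant anther transcripts along: of the 10 at 5000 TPM or more, the 4 that varied most between the B73 anthers allowed at most 0.062 to 0.320% of such RNA in ms28 germ cells, and the other 6, all higher in both ms28 than in both B73 germ cell libraries, at most 6.34 to 24.6%. Even by the closest libraries, 1263 of the 1890 rises would need more than 24.6%, and the median need was 39.7%. RNA of exactly this makeup must meet all 10 limits, so the lowest of them, 0.062%, is the one that binds. This argues against such RNA for every rise that needs more, and how many of the other 627 do was not counted. For these 627, RNA with less of those 4 transcripts cannot be told from a change in the cells. Less advanced cells may also raise features of premeiotic anthers. There the calls with centred values had a median percentile of 66.0 for the rises and 41.3 for the falls. The smallest gap in a premeiotic library exceeded the largest in a prophase I anther library by 3.37 points (24.6 against 21.2). That largest gap was in ms28 anther replicate 2. The gap was 20.3 in ms28 anther replicate 1, and 12.1 and 17.4 in the B73 prophase I anthers. How far changes shared by both tissues of ms28 widened the gaps in ms28 anthers was not tested. Less advanced cells, RNA of other anther cells with another makeup, other differences between the lines and an effect of ms28 on germ cells at the same stage are therefore not told apart.

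In the germ cell table alone, limma also called MIR395c, of the sulfate starvation response (0.590 ± 0.049 TPM in B73 and 3.24 ± 0.29 TPM in ms28; SD, n = 2; adjusted p = 0.0054), and MIR169o (5.58 ± 1.98 and 14.7 ± 6.15 TPM; adjusted p = 0.037). In the joint fit they were not called (adjusted p = 0.078 and 0.108). MIR167c, in the germ cell table only, read 1.85 and 1.35 TPM in B73 and was listed at 0 in both ms28 libraries (adjusted p = 0.0051). The order of rows in the anther table followed the absolute centred change (Spearman -0.816 across genes) more closely than the change in TPM as deposited (-0.153). For germ cells the 2 scales were alike in this (-0.857 centred and -0.850 as deposited).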
